A study of Mus musculus with 10 samples.

How the data were processed

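The data came from sorted GFP-positive cells of embryonic mouse cortex, 10 bulk RNA-seq libraries in 5 groups of 2. At E17.5, cells came from C57BL/6 wild-type (WT) cortex or from cortex with a Nestin-Cre conditional knockout of Ccn1 (CcKO). Both had been electroporated in utero at E14.5 with the control PiggyBac plasmid (PB-Ctrl). At E15.5, cells came from ICR cortex electroporated at E13.5 with PB-Ctrl, a CCN1 plasmid (PB-CCN1) or a GPC4 plasmid (PB-GPC4). PiggyBac is a transposon that, with its transposase, inserts the plasmid cargo into the genome. Plasmids were injected at 3 µg/µl for the transposase and 1.5 µg/µl for the PiggyBac construct. Per the labels, total RNA was taken up in TRIzol, mRNA libraries were made with the KAPA Hyper Prep kit, and sequencing ran on a NovaSeq.

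The authors processed the reads with bcl2fastq, Trimmomatic, HISAT2 and featureCounts on mm10, with no versions stated. The deposited values are raw read counts per Entrez gene ID, with no normalisation. The authors also gave FPKM, scaled to gene length and to the total of the counts. The lengths implied by the ratio of counts to FPKM deviated by 0 bases from 1 whole number per gene across the 10 libraries, so FPKM adds no information beyond the counts. The table held 27178 gene IDs, of which 93.1% were given a symbol, from RefSeq for 25274 and from GENCODE M21 for a further 18. The remaining 1886 stayed unnamed.

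Total counts ranged from 22505945 to 30825498 per library, which gives the depth behind every value. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom between 3.37 and 8.71 and Pearson's r of log2 counts between 0.979 and 0.985. A gene with all libraries of a group at 0 was given a floor of 3 counts per library, and its fold change is a lower bound. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say that replicates are separate animals or litters, so p-values measure the spread between these samples.

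Genes were tested with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on counts, with TMM normalisation, the filterByExpr filter and 5 group means in 1 model. Of the 27178 genes, 15371 were tested. The model had 5 residual degrees of freedom, a common dispersion of 0.00385 and a prior of 22.2 degrees of freedom. Adjusted p is by Benjamini-Hochberg over the genes tested, two-sided, with a threshold of 0.05 and no minimum fold. Levels are TMM-normalised CPM, given as mean ± SD with n = 2 libraries per group, and the error of a log2 fold change is its standard error (SE).

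Of 33 gene lists written before the data were examined, 30 were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. The preset correlation between genes was 0.01, and adjustment was over the 30 lists. They covered progenitor, neuronal, glial and other cell types, the cell cycle, signalling components and targets, stress, metabolism, ribosomal genes, proteoglycans, integrins with matrix, and the CCN family. The lists of mitochondrially encoded genes and of choroid plexus markers had fewer than 3 members matched by symbol among the tested genes, and sex-linked genes were read singly. The mitochondrial genes COX3 and ATP6 were tested under symbols other than those on the list and so were not matched. Ccn1 and Gpc4 were left out of every list. Camera was repeated with a correlation estimated from the data, and each list's genes were also adjusted over the list alone.

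The genes named were fixed by a rule. It took Ccn1 and Gpc4, and the 8 largest called rises and falls per comparison with a control (5 in the direct comparison of plasmids) at an average of at least 1 CPM, with both replicates of 1 group above both of the other. It left out predicted gene names. It added up to 4 called members of each list with the smallest adjusted p, or the 2 members with the smallest p where a called list had none. Genes outside it are marked in the text as chosen after their values were seen.

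Alternatives planned before the data were examined were size factors by relative log expression, no filter on low counts, a replicate block, each experiment fitted on its own, each library left out in turn, the DESeq2 Wald test (DESeq2 1.42.0) and limma on log2 of FPKM plus 1. For lists they also included camera with an estimated correlation and fry, and for correlations of fold changes the genes with an average log2 CPM of at least 5 and the genes called in at least 1 comparison. Pseudocount and filter alternatives planned for a table with FPKM alone did not apply and were not run. Removal of a smooth length and GC trend from every library was added after the data were seen. It used lowess with a span of 0.3 over gene length and the GC content of the longest GENCODE M21 transcript, known for 95.9% of tested genes.

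The test and the lists were checked on simulated data. Of genes changed 2-fold between 2 simulated groups of 2, between 74.6% and 80.6% were recovered with the right direction, and of the calls made, between 4.73% and 6.86% were unchanged genes. With 1 list moved by 0.4 on the log2 scale, camera called it in each of 4 simulated comparisons, and in 1 of them it also called 2 lists that had not been moved. Genes were drawn independently there, so the check does not cover list calls under correlation between genes. A simulated smooth trend of 0.15 log2 per doubling of length, without other change, gave 1612 calls before and 0 after its removal. The expected correlation between effects that share control libraries came from 50 simulations with unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, which with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 also read the files.

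Several choices followed after values had been seen. The level below which a lung gene counted as low at E17.5 was set with counts in view. The set of step-like genes above the floor in PB-GPC4 was formed after genes resembling lung genes were seen in the full set. The bound that would have excluded a plasmid response in those genes was widened after its value was known. The test of the length trend as the only cause was added after its count was known, and the test of maturity was also run on values with the trend removed. A sign change of a correlation near 0 was counted as a reversal only if it exceeded the spread over left-out libraries, a condition added after 3 such changes had been seen.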

Results

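Transcript levels were measured by bulk RNA-seq in GFP-positive cells sorted from mouse cortex, in 2 libraries of each of 5 groups. Total counts were 23175919 and 27646961 in WT, 25235270 and 27734988 in CcKO, 25642567 and 27985945 in PB-Ctrl, 22505945 and 23514678 in PB-CCN1, and 26061810 and 30825498 in PB-GPC4. Strain, age and day of electroporation differed between the E17.5 and E15.5 experiments, so each comparison of groups stayed within 1 experiment. The first component of the log2 CPM, with 52.7% of the variance, separated the 4 libraries at E17.5 from the 6 at E15.5. The second, with 9.88%, separated WT from CcKO.

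The targeted genes were first compared to see what knockout and plasmids did to their transcripts. Ccn1 (Entrez gene 16007, chromosome 3, 145646971 to 145649985 on GRCm38.p6) encodes a secreted matricellular protein. Its level was 14.9 ± 3.9 CPM in WT and 1.89 ± 1.7 CPM in CcKO (SD, n = 2), a log2 fold change of -2.93 (SE 0.24, edgeR adjusted p = 1.83e-10). CcKO replicates held 17 and 86 counts, and the log2 fold change was -4.47 without CcKO replicate 2 and -2.24 without CcKO replicate 1. At E15.5, Ccn1 stood at 53.9 ± 4.8 CPM in PB-Ctrl and rose to 7050 ± 67 CPM in PB-CCN1, a log2 fold change of 7.03 (SE 0.13, adjusted p = 1.06e-24). Gpc4 (Entrez gene 14735, chromosome X, 52051007 to 52164923) encodes a glypican, a heparan sulfate proteoglycan anchored in the membrane. It rose from 68.3 ± 3.1 CPM in PB-Ctrl to 5060 ± 80 CPM in PB-GPC4, a log2 fold change of 6.21 (SE 0.05, adjusted p = 3.9e-34). Reads of plasmid and endogenous origin are not separated in these counts.

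Each targeted gene was also read under the other manipulation. Ccn1 fell in PB-GPC4 to 33 ± 4.5 CPM, a log2 fold change of -0.71 (SE 0.12, edgeR adjusted p = 0.000488). That fall did not pass with DESeq2 (adjusted p = 0.57) or with limma on log2 of FPKM plus 1 (adjusted p = 0.154). Gpc4 was at 73.1 ± 0.9 CPM in PB-CCN1, a log2 fold change of 0.10 (SE 0.05, adjusted p = 0.431). It was at 44.6 ± 1.4 CPM in CcKO and 44.5 ± 0.8 CPM in WT, a log2 fold change of 0.00 (SE 0.05, adjusted p = 0.959).

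**Figure D1:**
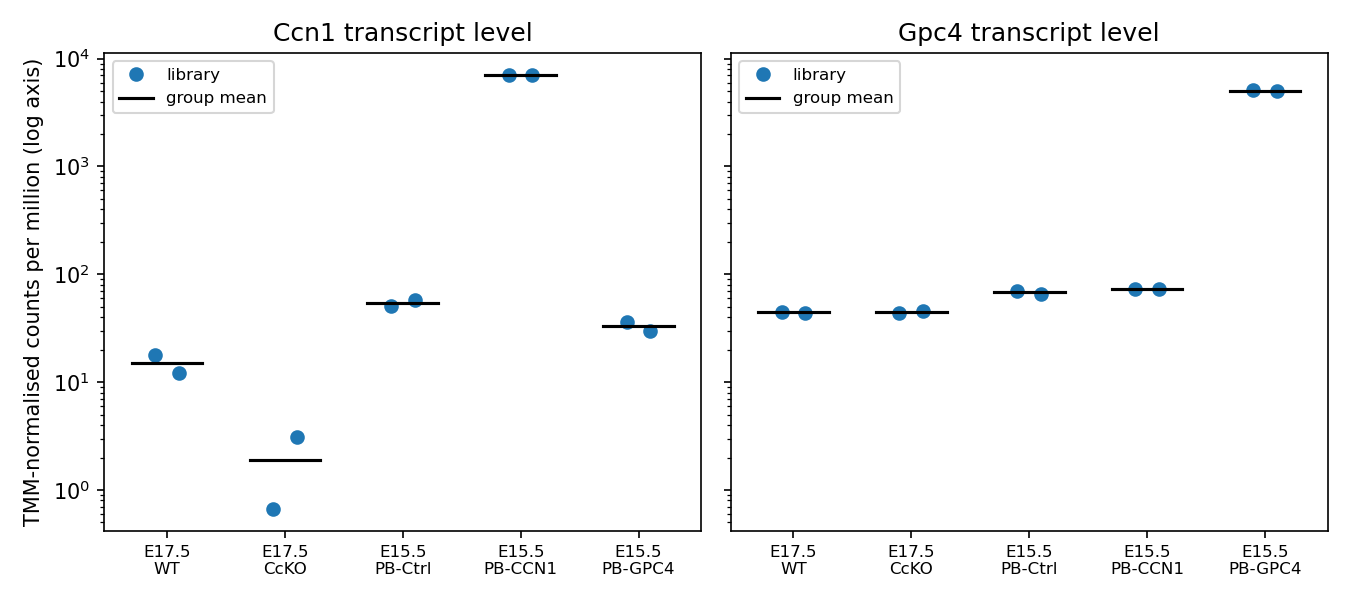
TMM-normalised CPM of Ccn1 and Gpc4 (log axis) in each of the 10 libraries (points), with group means (lines), for the 5 groups. Ccn1 lies near 7050 in PB-CCN1 and at 1.89 in CcKO, and Gpc4 lies near 5060 in PB-GPC4 and between 44.5 and 73.1 in the other groups.

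The comparison of CcKO with WT addressed what loss of Ccn1 does to cortical cells at E17.5. Several progenitor genes were higher in CcKO: Notch1, a receptor of progenitor maintenance, rose from 60.2 ± 2.3 to 131 ± 12 CPM (SD, n = 2), and Ptch1, a Hedgehog receptor and target, rose from 7.1 ± 0.4 to 18 ± 0.037 CPM. Tnc, an extracellular matrix protein of radial glia, rose from 175 ± 16 to 309 ± 0.43 CPM, and Mki67, a proliferation marker, from 142 ± 5.6 to 221 ± 0.22 CPM. Most listed genes of cytosolic ribosomal proteins were lower. By edgeR, 2676 genes rose and 1987 fell, 4663 in all. Of these, 340 rose and 77 fell by at least 2-fold.

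The radial glia and cell-cycle lists rose in CcKO. Of 20 radial glia genes, 12 rose, 0 fell and 8 did not pass, and adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 2e-04, and adjusted p = 0.218 with an estimated correlation). Ddah1 rose 1.53-fold, Slc1a3, a glutamate transporter, 1.40-fold, and Ptprz1 1.37-fold. Of 20 DNA replication genes, 7 rose, and 8 adjusted over the list alone (camera adjusted p = 0.0195, and adjusted p = 0.218 with an estimated correlation). The helicase subunits Mcm2 and Mcm3 rose 1.56-fold and 1.42-fold. Of 20 mitosis genes, 10 rose, with the same count adjusted over the list alone (camera adjusted p = 0.000494, and adjusted p = 0.462 with an estimated correlation). Top2a and Kif11 each rose 1.30-fold. Of 15 intermediate progenitor genes, 3 rose and 4 fell, and 5 rose and 4 fell adjusted over the list alone, and the list did not pass (camera adjusted p = 0.95). Without CcKO replicate 2 the DNA replication and mitosis lists were not called (adjusted p = 0.0628 and 0.0655). Xist stood 1.46-fold higher in CcKO than in WT (adjusted p = 5.46e-05), with a log2 fold change of -0.04 once a trend with length and GC content was removed. The Y-linked Eif2s3y was lower in CcKO (log2 fold change -0.53, adjusted p = 0.0206) and did not pass after that removal (log2 fold change -0.40, adjusted p = 0.106), while Ddx3y, Kdm5d and Uty did not pass (adjusted p = 0.797, 0.792 and 0.906).

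The Hedgehog, FGF and ERK, and YAP lists rose as well. Of 9 Hedgehog genes, 6 rose, and 8 adjusted over the list alone (camera adjusted p = 7.55e-05, and adjusted p = 0.0887 with an estimated correlation). Besides Ptch1, the transcription factor Gli3 rose 1.64-fold, and the surface proteins Gas1 and Cdon rose 1.56-fold and 1.39-fold. The Hedgehog list joins components of the pathway with its targets, so its direction in any comparison is not a measure of pathway activity. Of 12 FGF and ERK genes, 8 rose, and 10 adjusted over the list alone (camera adjusted p = 2e-04, and adjusted p = 0.218 with an estimated correlation). Etv5, a transcription factor induced by ERK, rose 1.94-fold, and the feedback inhibitors Spred1, Spred2 and Dusp4 rose 1.74-fold, 1.73-fold and 1.59-fold. Of 11 YAP target genes, 6 rose, and 7 adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.218 with an estimated correlation), with Lats2, a kinase of the Hippo pathway, up 1.74-fold. Of 12 Notch genes, 4 rose, and 5 adjusted over the list alone, among them Notch1 and Notch3 (2.18-fold and 1.94-fold), while the list did not pass (camera adjusted p = 0.0617).

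Matrix, layer neuron and ribosomal lists changed in part with transcript length, and the newborn neuron list did not pass (camera adjusted p = 0.934). Of 19 integrin and matrix genes, 10 rose, and 11 adjusted over the list alone (camera adjusted p = 2e-04, and adjusted p = 0.0887 with an estimated correlation). Itga6 and the laminin chain gene Lamc1 rose 1.66-fold and 1.55-fold. Of 23 proteoglycan genes, 8 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0251, and adjusted p = 0.218 with an estimated correlation). Ndst1, an enzyme of heparan sulfate sulfation, rose 1.71-fold. That list was not called without WT replicate 1 or CcKO replicate 2 (adjusted p = 0.0879 and 0.0794). Of 15 deep-layer genes, 8 rose, with the same count adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.462 with an estimated correlation), with Bcl11b up 1.63-fold. It was not called without CcKO replicate 2 (adjusted p = 0.0606). Of 15 upper-layer genes, 8 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.355 with an estimated correlation), with Epha3 and Cux2 up 1.52-fold and 1.28-fold. Of 25 ribosomal protein genes, 24 fell, with the same count adjusted over the list alone (camera adjusted p = 2.56e-17, and adjusted p = 0.218 with an estimated correlation), and Rpl18 fell by 0.48 on the log2 scale.

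Fold changes followed transcript length across genes (Spearman's rho = 0.434, genes not being independent replicates), with a median log2 fold change of -0.28 in the shortest decile and 0.33 in the longest. With that trend and the trend with GC content removed, 2787 genes were called (1487 higher and 1300 lower), of which 2117 were shared in direction with the 4663. After removal 6 ribosomal genes were lower and 1 higher (camera adjusted p = 0.0111), the Notch and immediate-early lists were called (adjusted p = 0.0111 and 0.0391), and the upper-layer, YAP and proteoglycan lists were not (adjusted p = 0.0986, 0.0835 and 0.228). Without the removal the Notch and immediate-early lists did not pass (camera adjusted p = 0.0617 and 0.481, and 0.355 and 0.762 with an estimated correlation). Values with an estimated correlation after the removal were not kept, so those 2 calls rest on the preset correlation. Log2 fold changes shrank from 1.34 to 1.19 for Ptch1, 1.12 to 0.81 for Notch1, 0.82 to 0.57 for Tnc and 0.63 to 0.22 for Mki67, and all 4 still passed (adjusted p = 2.25e-07, 3e-10, 4.93e-08 and 0.000565). Folds of CcKO over WT, above and below, are without the removal unless stated. Others that shrank were Ptprz1 (0.45 to 0.13), Gli3 (0.72 to 0.37), Cdon (0.48 to 0.18) and Bcl11b (0.71 to 0.39). The same held for Lamc1 (0.64 to 0.36) and Top2a (0.38 to 0.19). Gas1 (0.64 to 0.68) and Dusp4 (0.67 to 0.75) did not shrink, nor did Spred2 (0.79) and Mcm3 (0.51). The count was 2919 without WT replicate 2, and limma on log2 of FPKM plus 1 gave 4169 genes, 2037 higher and 2132 lower, so the balance of directions turned.

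The comparison of PB-CCN1 with PB-Ctrl addressed what excess CCN1 does to cells at E15.5. Some Hedgehog and radial glia genes were lower in PB-CCN1: Gli1, a transcription factor and target of the Hedgehog pathway, fell from 16.8 ± 0.67 to 7.73 ± 0.22 CPM (SD, n = 2), and Tnc fell from 129 ± 0.52 to 87.2 ± 1.3 CPM. Ccn2, another CCN family member and a YAP target, fell from 8.82 ± 0.47 to 2.03 ± 0.8 CPM. Slc7a11, a cystine transporter, rose from 15.2 ± 1.3 to 64.7 ± 3.7 CPM, and Plk2, a kinase on the p53 list, from 171 ± 2.9 to 259 ± 2 CPM. The rise of Slc7a11 did not pass with DESeq2 (adjusted p = 0.0924). By edgeR, 68 genes rose and 115 fell, 183 in all.

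The radial glia, Hedgehog, Notch, integrin and matrix, and both cell-cycle lists fell in PB-CCN1, with few members called. The intermediate progenitor, FGF and ERK, and YAP lists did not pass (camera adjusted p = 0.776, 0.0514 and 0.0514). Of 20 radial glia genes, 3 fell (Tnc, Nes and Slc1a3), and 9 adjusted over the list alone (camera adjusted p = 4.49e-09, and adjusted p = 0.098 with an estimated correlation). Of 9 Hedgehog genes, 3 fell, and 6 adjusted over the list alone (camera adjusted p = 2.74e-07, and adjusted p = 0.0419 with an estimated correlation). Gli1, Gas1 and Gli3 changed by -1.12, -0.34 and -0.27 on the log2 scale, and Gli3 did not pass once the length and GC trend was removed (adjusted p = 0.0965). Of 20 DNA replication genes, 1 fell (Mcm3), and 9 adjusted over the list alone (camera adjusted p = 3.35e-08, and adjusted p = 0.0419 with an estimated correlation). Of 20 mitosis genes, 1 fell (Top2a), and 3 adjusted over the list alone (camera adjusted p = 9.37e-06, and adjusted p = 0.243 with an estimated correlation). Of 12 Notch genes, 2 fell, and 7 adjusted over the list alone (camera adjusted p = 0.000202, and adjusted p = 0.0982 with an estimated correlation). These were Id4 (0.759 of the control level) and Notch1 (0.826), and Notch1 did not pass after the trend was removed (adjusted p = 0.0645). Of 19 integrin and matrix genes, 1 fell (Tnc), with the same count adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.102 with an estimated correlation). Xist stood 1.62-fold higher in PB-CCN1 than in PB-Ctrl (adjusted p = 4.54e-05). The Y-linked Ddx3y, Kdm5d, Eif2s3y and Uty had log2 fold changes of -0.49, -0.55, -0.33 and -0.47. None of them passed (edgeR adjusted p = 0.2, 0.159, 0.474 and 0.271). The labels do not give the sex of the embryos, so differences in sex-linked genes cannot be read as effects of a manipulation in any comparison.

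Stress genes moved in both directions. Of 18 immediate-early genes, 2 fell (Jun and Atf3) and 1 rose (Fos), and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.39e-05, and adjusted p = 0.102 with an estimated correlation). The rise of Fos did not pass with DESeq2 (adjusted p = 0.335). Of 14 genes of the unfolded protein and integrated stress responses, 2 rose, the chaperone gene Hspa5 (1.19-fold) and Herpud1 (1.28-fold), and 6 adjusted over the list alone (camera adjusted p = 6.15e-07, and adjusted p = 0.102 with an estimated correlation). The heat shock genes Hspa1b and Hspa1a changed by -4.04 and -3.61 on the log2 scale. Hspa1b stood at 26.5 and 23.7 CPM in PB-Ctrl, against 1.25 to 3.8 CPM in the other 8 libraries, so PB-Ctrl stood apart from every other group. Both genes are near-identical copies. Lypd10 fell from 20 ± 1.8 to 4.23 ± 0.54 CPM and had 0 counts in each of the 4 E17.5 libraries of the other strain.

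Other lists moved without a member passing, or with 1. The newborn neuron list rose with 0 of 16 members called and 0 adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.238 with an estimated correlation), at a median log2 fold change of 0.07. Of 25 ribosomal genes, 1 rose, with the same count adjusted over the list alone (camera adjusted p = 9.68e-05, and adjusted p = 0.307 with an estimated correlation). Its member was Rps2, up 1.48-fold. The interneuron list, markers of another cell type, fell with 0 of 14 members called and 4 adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.196 with an estimated correlation). The interferon list fell with 0 of 16 called and 1 adjusted over the list alone (camera adjusted p = 0.00215, and adjusted p = 0.191 with an estimated correlation). The glycolysis list fell with 0 of 16 called and 2 adjusted over the list alone (camera adjusted p = 4.72e-05, and adjusted p = 0.098 with an estimated correlation). The erythroid list fell with 0 of 4 called and 1 adjusted over the list alone (camera adjusted p = 0.021, and adjusted p = 0.181 with an estimated correlation). It was not called without any 1 library other than PB-GPC4 replicate 1 (adjusted p from 0.0505 to 0.262).

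The count of 183 was 56 and 61 without PB-Ctrl replicate 1 or 2, 74 and 72 without PB-CCN1 replicate 1 or 2, 282 and 283 without CcKO replicate 1 or 2, 298 without a filter on low counts, 537 with the E15.5 experiment alone and 31 with limma on log2 of FPKM plus 1. Of 34 single calls read again with limma, 13 passed, among them Tnc, Ccn2, Slc7a11 and Mcm3, and 21 did not, among them Gli1, Gas1, Gli3, Nes, Slc1a3, Notch1, Id4, Top2a, Jun, Atf3, Fos, Plk2, Hspa5 and Herpud1 (adjusted p from 0.0563 to 0.325 for these 14).

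The comparison of PB-GPC4 with PB-Ctrl addressed what excess GPC4 does at the same age. Some radial glia and Notch genes were lower and some neuronal genes higher in PB-GPC4: Tnc fell from 129 ± 0.52 to 75 ± 7.2 CPM (SD, n = 2), Hes5, a Notch effector, from 16.6 ± 1.7 to 10.3 ± 1.1 CPM, and Unc5d, a netrin receptor, rose from 311 ± 0.7 to 377 ± 3.7 CPM. Slc7a11 rose from 15.2 ± 1.3 to 97.8 ± 22 CPM and Trib3, a stress-induced pseudokinase, from 1.13 ± 0.51 to 4.56 ± 0.28 CPM. By edgeR, 491 genes rose and 487 fell, 978 in all.

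A group of 4 lists fell and passed with either correlation. Of 20 radial glia genes, 9 fell, and 14 adjusted over the list alone (camera adjusted p = 1.48e-12, and adjusted p = 0.0432 with an estimated correlation). Aldoc, Slc1a3 and Nes were at 0.716, 0.737 and 0.765 of the control level. Of 12 Notch genes, 6 fell, and 7 adjusted over the list alone (camera adjusted p = 9.4e-07, and adjusted p = 0.0432 with an estimated correlation). Id4, Notch3 and Lfng were at 0.624, 0.602 and 0.643 of control. Of 9 Hedgehog genes, 5 fell, and 6 adjusted over the list alone (camera adjusted p = 2.23e-07, and adjusted p = 0.0329 with an estimated correlation), among them Gli1, Gas1 and Cdon at 0.531, 0.703 and 0.803 of control. Of 18 immediate-early genes, 12 fell, and 14 adjusted over the list alone (camera adjusted p = 4.03e-18, and adjusted p = 0.0329 with an estimated correlation). Jun, Fosb and Nr4a1 were at 0.590, 0.649 and 0.483 of control. Beside these falls, Hspa1b and Hspa1a changed by -3.73 and -3.18 on the log2 scale, and Xist stood 1.78-fold higher in PB-GPC4 (adjusted p = 1.51e-06) and the Y-linked Kdm5d and Eif2s3y at 0.623 and 0.674 of control (adjusted p = 0.015 and 0.0451).

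The newborn neuron, intermediate progenitor, stress response, ribosomal and mitosis lists rose in PB-GPC4, while the upper-layer and deep-layer neuron lists did not pass (camera adjusted p = 0.135 and 0.646). Of 16 newborn neuron genes, 6 rose, and 10 adjusted over the list alone (camera adjusted p = 2.23e-07, and adjusted p = 0.138 with an estimated correlation). Neurod1, Tubb3 and Dcx rose by 0.27, 0.19 and 0.19 on the log2 scale. Of 15 intermediate progenitor genes, 5 rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0233, and adjusted p = 0.515 with an estimated correlation). Elavl4, an RNA-binding protein gene also expressed in neurons, and Gadd45g rose 1.27-fold and 1.24-fold. Of 14 genes of the unfolded protein and integrated stress responses, 8 rose, with the same count adjusted over the list alone (camera adjusted p = 4.93e-07, and adjusted p = 0.133 with an estimated correlation). Chac1, Herpud1 and Asns rose 2.12-fold, 1.61-fold and 1.51-fold. Of 25 ribosomal genes, 5 rose, and 6 adjusted over the list alone (camera adjusted p = 0.000696, and adjusted p = 0.45 with an estimated correlation), with Rps2 up 1.44-fold. Of 20 mitosis genes, 2 rose, Kif11 and Mki67, with the same count adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.515 with an estimated correlation). The DNA replication list did not rise: of 20 genes 0 were called, and 3 were lower adjusted over the list alone. Camera ranked it low without a call (adjusted p = 0.0963, and adjusted p = 0.338 with an estimated correlation). It was called as lower after the length and GC trend was removed (camera adjusted p = 0.0379). The mitosis list was not called without PB-Ctrl replicate 2 or PB-GPC4 replicate 1, or after the length and GC trend was removed (adjusted p = 0.138, 0.0725 and 0.0784).

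A further 3 lists fell in PB-GPC4. Of 14 interneuron genes, 4 fell, with the same count adjusted over the list alone (camera adjusted p = 0.00166, and adjusted p = 0.278 with an estimated correlation), among them Sst and Lhx6 at 0.260 and 0.549 of control. Of 11 YAP target genes, 1 fell, and 3 adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.212 with an estimated correlation). Of the 4 measured CCN family genes other than Ccn1, 1 fell, and 2 adjusted over the list alone (camera adjusted p = 0.0481, and adjusted p = 0.212 with an estimated correlation). The called member was Ccn2 in both, at 0.327 of control. Without a filter on low counts neither passed (adjusted p = 0.0896 and 0.137), and leaving out single libraries ended the calls in 8 and 6 of 10 cases (adjusted p up to 0.199 and 0.0889). The YAP list was not called after the length and GC trend was removed (adjusted p = 0.129), nor the CCN family list with a replicate block or with the E15.5 experiment alone (adjusted p = 0.0526 and 0.0705).

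The largest falls in PB-GPC4 were genes of lung epithelium. Scgb1a1, a secretoglobin of airway club cells, stood at 36.6 ± 4.5 CPM in PB-Ctrl and at 0 counts in both PB-GPC4 libraries, at least 340-fold lower. Cyp2f2, a cytochrome P450 of the same cells, was at least 69.9-fold lower. Sftpc, a surfactant protein gene, fell from 9.5 ± 1 to 0.0656 ± 0.093 CPM. Scgb1a1 was at 40.5 ± 0.71 CPM in PB-CCN1 and at 0 counts in all 4 E17.5 libraries. Of 26 tested genes on a list of lung markers, written after these falls were seen, 15 were lower in PB-GPC4 than in PB-Ctrl.

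**Figure D2:**
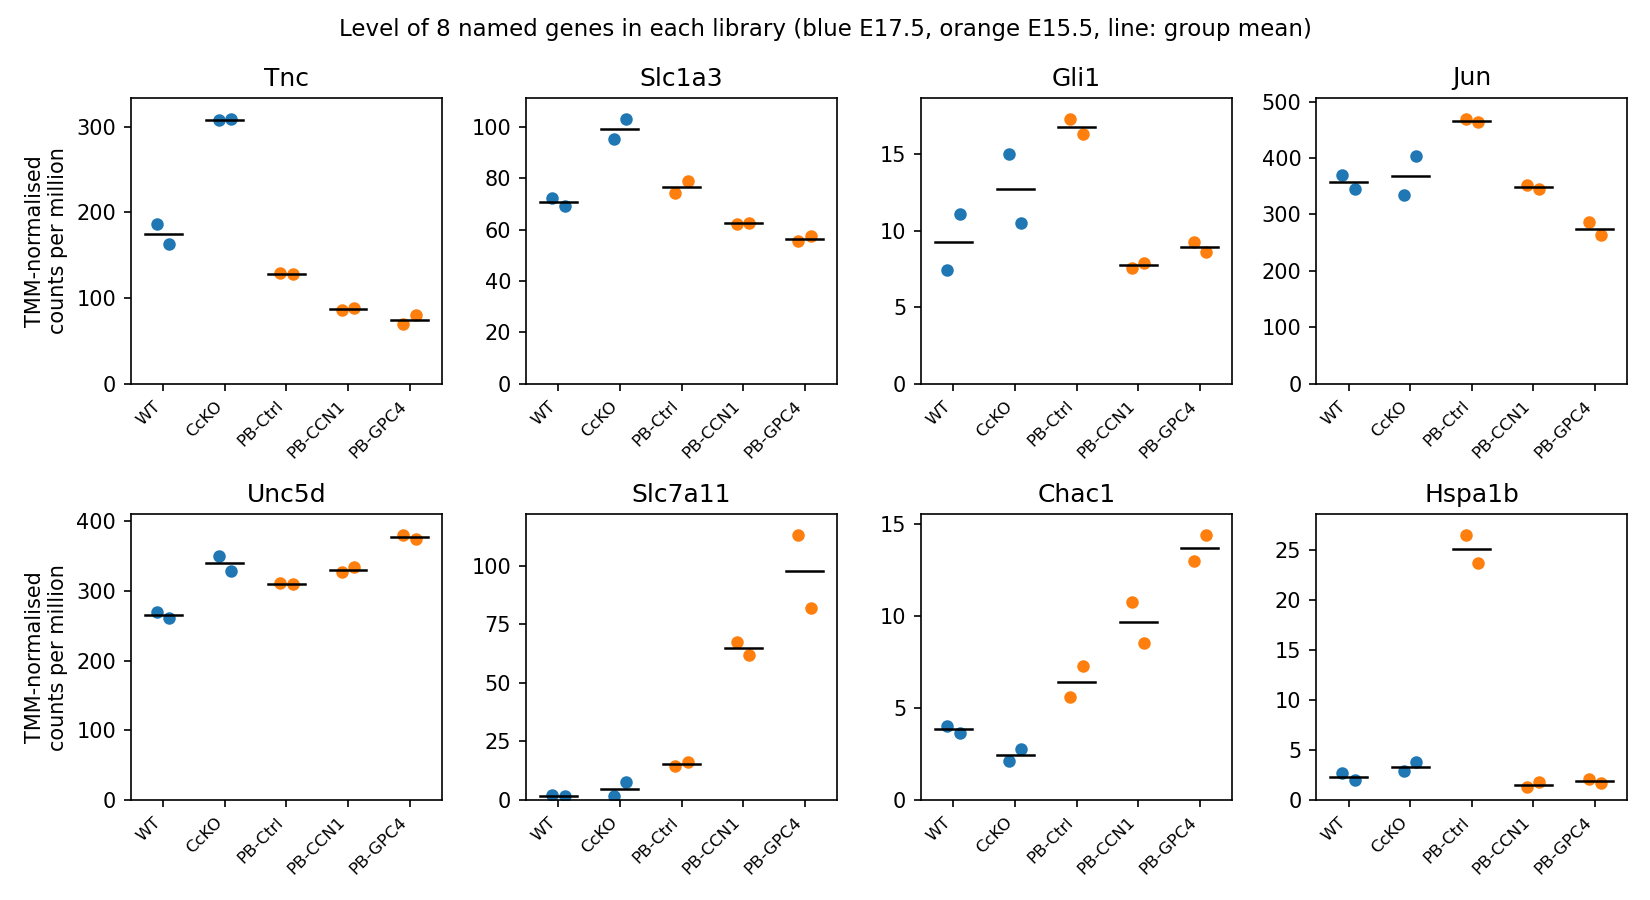
TMM-normalised CPM of 8 named genes in each library (points; blue E17.5, orange E15.5), with group means (lines). The 8 were picked for the plot after their values were seen. Tnc lies at 309 in CcKO and at 75 in PB-GPC4, and Hspa1b lies near 25.1 in PB-Ctrl and at 3.8 or below in every other library.

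The count of 978 was 311 and 284 without PB-Ctrl replicate 1 or 2, 350 and 336 without PB-GPC4 replicate 1 or 2, 1475 without CcKO replicate 2, 2006 with the E15.5 experiment alone and 374 with limma on log2 of FPKM plus 1, where 35 of 75 single calls did not pass, among them Hes5, Neurod1, Tubb3, Dcx, Gadd45g, Kif11, Mki67, Lhx6, Reln, Nkd1 and Axin2 (adjusted p from 0.0605 to 0.177 for these 11). The share that was higher, 50.2%, was 63.4% after the length and GC trend was removed, 63.6% without a filter and 62.1% with DESeq2, but 36.4% with limma and 41.4% without PB-GPC4 replicate 1.

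The direct comparison of PB-CCN1 with PB-GPC4 addressed where the plasmids differ, free of the shared controls. Of 18 immediate-early genes, 8 were higher in PB-CCN1 than in PB-GPC4, and of 20 mitosis genes, 3 were lower, and neither list passed with an estimated correlation (camera adjusted p = 0.132 and 0.304). Nr4a1, an orphan nuclear receptor induced early by stimulation, was at 22.4 ± 0.31 CPM in PB-CCN1 and 11.2 ± 0.71 CPM in PB-GPC4 (SD, n = 2), and Top2a, a topoisomerase of dividing cells, was at 225 ± 1.2 and 290 ± 3.4 CPM. By edgeR, 215 genes were higher and 116 lower in PB-CCN1, 331 in all. Ccn1 and Gpc4 themselves differed by 7.74 and -6.11 on the log2 scale.

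List members named in the direct comparison were chosen after their values were seen. Of 18 immediate-early genes, 8 were higher in PB-CCN1, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.96e-10, and adjusted p = 0.132 with an estimated correlation). Besides Nr4a1, Fosb and Fos differed by 0.69 and 0.65 on the log2 scale. Of 20 mitosis genes, 3 were lower, Top2a, Kif11 and Mki67, and 7 adjusted over the list alone (camera adjusted p = 2.66e-10, and adjusted p = 0.304 with an estimated correlation). Of 20 DNA replication genes, 0 were called, and 1 was lower adjusted over the list alone (camera adjusted p = 0.00219, and adjusted p = 0.249 with an estimated correlation). Of 20 radial glia genes, 2 were higher, Hes5 and Aldoc, and 4 adjusted over the list alone (camera adjusted p = 0.00219, and adjusted p = 0.351 with an estimated correlation). Of 12 Notch genes, 2 were higher, Hes5 and Notch3, and 3 adjusted over the list alone (camera adjusted p = 0.0216, and adjusted p = 0.304 with an estimated correlation). The Notch list was not called without PB-CCN1 replicate 2 or PB-GPC4 replicate 2, or after the length and GC trend was removed (adjusted p = 0.0654, 0.0783 and 0.133).

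The newborn neuron, intermediate progenitor, glycolysis and microglia lists were lower in PB-CCN1 than in PB-GPC4. Of 16 newborn neuron genes, 2 were lower, Nrp1 and Unc5d, and 4 adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.371 with an estimated correlation). Of 15 intermediate progenitor genes, 1 was lower, Elavl4, and 5 adjusted over the list alone (camera adjusted p = 0.00107, and adjusted p = 0.596 with an estimated correlation). That list was not called without PB-CCN1 replicate 2 (adjusted p = 0.0617). Of 16 glycolysis genes, 1 was lower, Ldha, and 4 adjusted over the list alone (camera adjusted p = 0.00107, and adjusted p = 0.249 with an estimated correlation). Of 12 microglia and macrophage genes, 2 were lower, the complement gene C1qc and the receptor gene Csf1r, and 1 was higher, Lyz2, which also stands on the lung list. Adjusted over the list alone, 3 were lower and 1 higher (camera adjusted p = 0.00107, and adjusted p = 0.249 with an estimated correlation). Of the lung list, 16 of 26 tested genes were called.

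The count of 331 was 77 and 150 without PB-CCN1 replicate 1 or 2, 121 and 89 without PB-GPC4 replicate 1 or 2, 220 without PB-Ctrl replicate 1, 596 and 593 without CcKO replicate 1 or 2, 589 without a filter, 990 with the E15.5 experiment alone and 64 with limma on log2 of FPKM plus 1. The share that was higher in PB-CCN1, 65%, was 48.7% after the length and GC trend was removed, 47% with DESeq2, 45.7% without a filter and 48.6% without CcKO replicate 2, but 67.2% with limma and 71.4% without PB-CCN1 replicate 1.

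**Figure D3:**
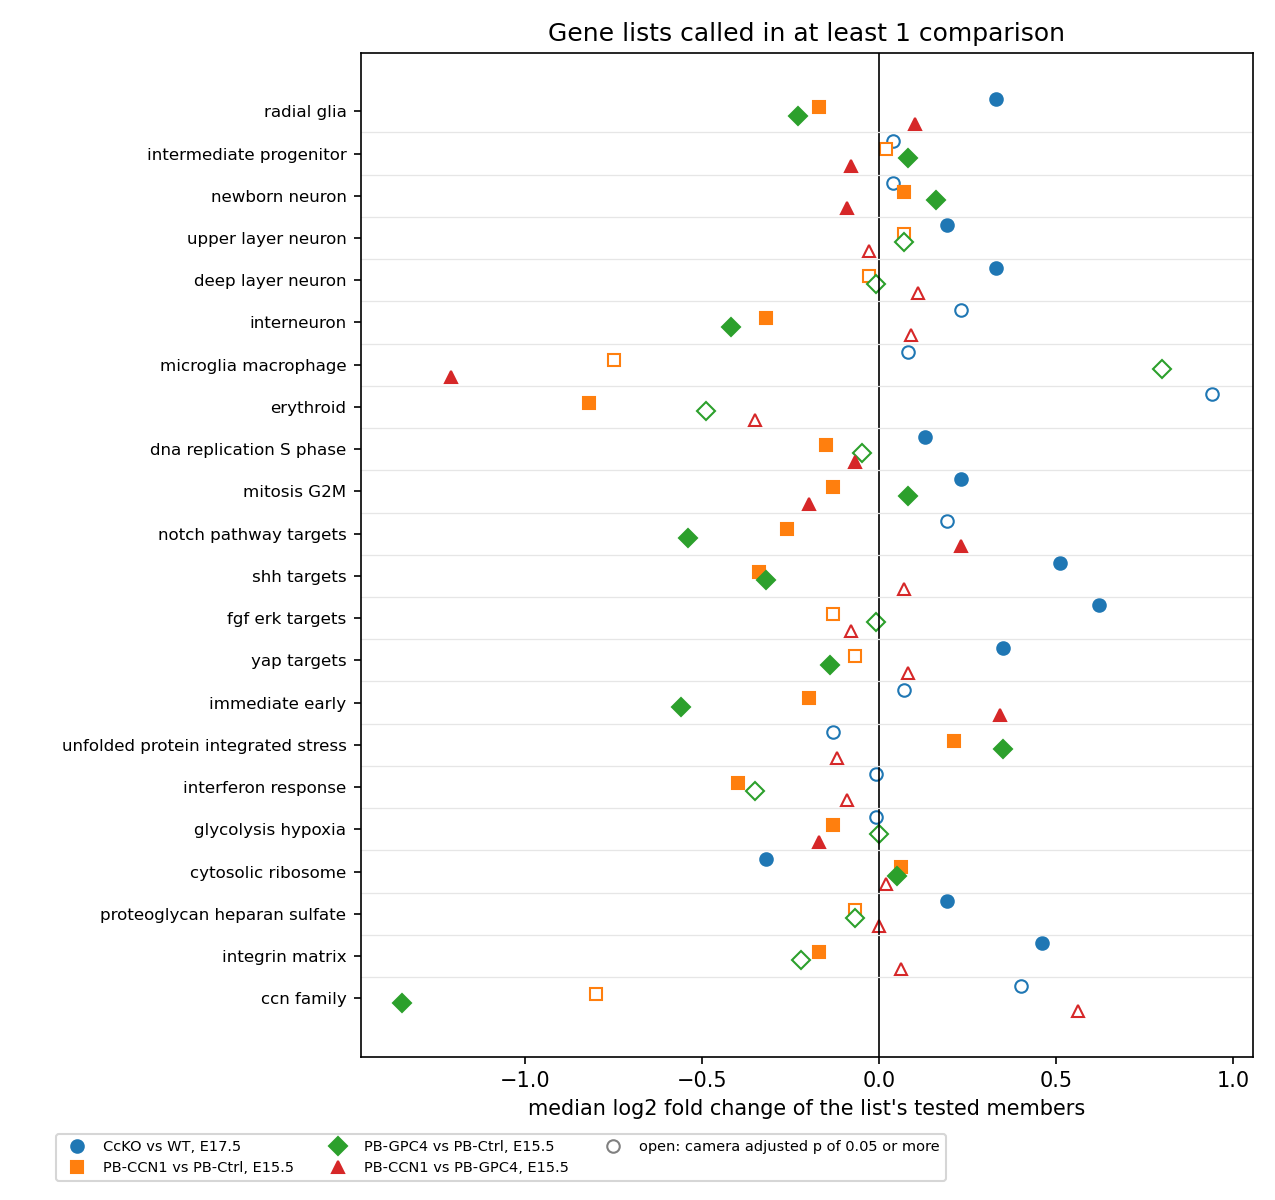
Median log2 fold change of the tested members of each gene list (x axis) for the lists called in at least 1 comparison (y axis), with 1 symbol per comparison, filled where the camera adjusted p with the preset correlation was under 0.05. The Hedgehog list lies at 0.51 in CcKO, -0.34 in PB-CCN1 and -0.32 in PB-GPC4.

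The effects of both plasmids were compared across genes, which are not independent replicates. Log2 fold changes of PB-CCN1 and PB-GPC4, each against PB-Ctrl, had Pearson's r = 0.413, Spearman's rho = 0.483 and a covariance of 0.122. For comparison, unchanged groups and their 2 shared control libraries were all simulated from the fitted PB-Ctrl means. They gave a mean r of 0.488 (0.447 to 0.533 over 50 simulations) and a mean covariance of 0.0655. So r itself did not exceed what shared controls give, while the covariance exceeded its simulated mean. A shift of the real PB-Ctrl libraries as a group is not in these simulations. Calls overlapped beyond independence, a measure the shared controls also raise: 32 genes rose in both, against 2.14 expected, and 71 fell in both, against 3.64 expected. The simulated unchanged groups shared 0 calls in each of the 50 simulations, by a likelihood-ratio test with the dispersion given. That value leaves out the effects and any shift of PB-Ctrl as a group, while the expected numbers leave out the shared controls. Gli1, Tnc, Ccn2 and Jun were among the genes that fell in both, and Slc7a11, Rps2 and Hspa5 among those that rose.

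Loss and excess of Ccn1 were compared with libraries that are not shared. Across genes, the CcKO and PB-CCN1 effects had r = -0.00112 and rho = -0.127, and r was -0.209 among genes with an average log2 CPM of at least 5. Of the calls, 46 genes were higher in CcKO and lower in PB-CCN1, against 20 expected (odds ratio 3.2, Fisher's exact test, two-sided, p = 8.77e-09). Tnc, Slc1a3, Notch1, Gli3, Gas1, Mcm3 and Ccnd1 were among them. Of these 46 genes, 31 were also lower in PB-GPC4, but so were 71 of all 115 genes lower in PB-CCN1. Both plasmid effects use the same PB-Ctrl libraries, so the 31 are not a separate reading of the 46. Of the 46, 22 were called in CcKO and in PB-CCN1 after the length and GC trend was removed. With the trend removed from both, that pair of directions held 25 genes, against 11 expected (Fisher's exact test, two-sided, p = 8.23e-05). Genes lower in CcKO and higher in PB-CCN1 numbered 10, against 8.66 expected (Fisher's exact test, two-sided, p = 0.585), and 14 after the removal, against 7.44 expected (odds ratio 2.06, Fisher's exact test, two-sided, p = 0.0191).

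With PB-GPC4 the overlap was not confined to opposite directions: 147 genes were higher in CcKO and lower in PB-GPC4 (84.6 expected), 123 lower and higher (63.3 expected), 110 higher in both (85.3 expected) and 68 lower in both (62.8 expected; Fisher's exact test, two-sided, p = 0.492). After the length and GC trend was removed, the counts exceeded expectation for each of the 4 pairs of directions. They were 61 higher in CcKO and lower in PB-GPC4 (37.1 expected, odds ratio 1.8), 99 lower and higher (56.1 expected, odds ratio 1.97), 103 higher in both (64.2 expected, odds ratio 1.77) and 71 lower in both (32.4 expected, odds ratio 2.55, Fisher's exact test, two-sided, p = 2.85e-10). The exact tests treat genes as independent, and 8 pairs of directions were tested with CcKO.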

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

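The 3 lists here came from a test planned before the data were examined, and the list members named were chosen only after the result was seen. In each, camera ranked PB-CCN1 low and PB-GPC4 high against the shared control, called in both for the mitosis list alone, and the direct comparison of the plasmids passed with the preset correlation.

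The mitosis list fell in PB-CCN1 and rose in PB-GPC4, with a direct camera adjusted p = 2.66e-10. With an estimated correlation none of these passed (adjusted p = 0.243 in PB-CCN1, 0.515 in PB-GPC4 and 0.304 directly). Median log2 fold changes were -0.13 against control in PB-CCN1, 0.08 in PB-GPC4 and -0.20 in the direct comparison. The DNA replication list, the other cell-cycle list, did not rise in PB-GPC4 (median log2 fold change -0.05, camera adjusted p = 0.0963). The rise in PB-GPC4 was not called without PB-Ctrl replicate 2 (adjusted p = 0.138) or PB-GPC4 replicate 1 (adjusted p = 0.0725), or after the length and GC trend was removed (adjusted p = 0.0784).

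The intermediate progenitor list had a direct camera adjusted p = 0.00107 and adjusted p = 0.596 with an estimated correlation. Only the rise in PB-GPC4 was called against control (camera adjusted p = 0.0233, and adjusted p = 0.515 with an estimated correlation), at a median log2 fold change of 0.08. In PB-CCN1 the median was 0.02, the mean -0.05 and the adjusted p = 0.776, so no direction can be read there. Without PB-CCN1 replicate 2 the direct difference was not called (adjusted p = 0.0617).

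The microglia and macrophage list had a direct camera adjusted p = 0.00107 and adjusted p = 0.249 with an estimated correlation. Neither effect against control was called (adjusted p = 0.104 in PB-CCN1 and 0.082 in PB-GPC4). C1qc stood at 0.805 CPM in PB-Ctrl, 0.415 in PB-CCN1 and 2.12 in PB-GPC4, where its replicates held 33 and 90 counts, and Csf1r at 1.41, 0.707 and 2.49 CPM. The direct difference of C1qc did not pass with limma on log2 of FPKM plus 1 (adjusted p = 0.0967). Lyz2, which is also on the lung list, went the other way, at 3.83, 4.39 and 1.29 CPM, and was the only member called against control in PB-GPC4 (edgeR adjusted p = 0.00705).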

How the results depend on the processing

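The length and GC correction was chosen only after the data were seen, and all other alternatives were planned. Not every alternative covers every result. Lists were not read with DESeq2 or limma on FPKM, nor the effect of each manipulation on its own target with limma. The correlations were read by expression, among called genes, with RLE factors, a replicate block and the length and GC correction, and over left-out libraries. Of the 230 results for named genes, DESeq2 and limma cover 219 each and the experiments on their own 228. The cause of a shift was not tested except where fewer libraries or genes show it. When 1 library is left out, the lone library of its group is assumed to vary like the other groups. The log2 fold changes of the gene targeted in each manipulation kept their direction and passed under every alternative run, from -4.47 to -2.24 for Ccn1 in CcKO, 6.94 to 7.12 for Ccn1 in PB-CCN1 and 6.17 to 6.27 for Gpc4 in PB-GPC4 over left-out libraries. Ccn1 in PB-GPC4, not its target, did not pass with DESeq2 or limma (adjusted p = 0.57 and 0.154).

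Leaving out 1 library gave 2919 to 4585 called genes in CcKO (main count 4663), 56 to 283 in PB-CCN1 (183), 284 to 1475 in PB-GPC4 (978) and 77 to 596 in the direct comparison (331). The low counts of the E15.5 comparisons came without a library of a compared group, which leaves fewer samples. The length and GC correction gave 2787 in CcKO. No filter on low counts gave 298 in PB-CCN1 and 589 directly. Each experiment on its own gave 537 in PB-CCN1, 2006 in PB-GPC4 and 990 directly. Limma on log2 of FPKM plus 1 gave 31, 374 and 64, and 4169 in CcKO, with 2037 higher and 2132 lower. The share that was higher in PB-GPC4, 50.2% of calls, moved both ways, to 62.1% with DESeq2 (643 higher and 392 lower) and to 36.4% with limma (136 higher and 238 lower).

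Replicate numbers did not pair samples across groups, as deviations of equally numbered libraries correlated at -0.02 to 0.02, and a replicate block gave 4811, 202, 1100 and 378 called genes.

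With an estimated correlation camera called 0 lists in CcKO (6 at an unadjusted p under 0.05), 2 in PB-CCN1, 4 in PB-GPC4 and 0 directly (4 unadjusted), and fry called 16, 8, 10 and 3. Leaving out 1 library gave 7 to 14 called lists directly, with 14 without PB-GPC4 replicate 1. The erythroid list in PB-CCN1 turned direction without a filter (adjusted p = 0.966).

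The correlation of the plasmid effects was 0.578 at an average log2 CPM of at least 5 and 0.33 to 0.64 over left-out libraries, with 0.625 and 0.64 without PB-Ctrl replicate 1 or 2. Unchanged groups were not simulated for these settings, so the values cannot be set against what shared controls give. That of the CcKO and PB-CCN1 effects was -0.209 at high expression, -0.0439 to 0.000809 over left-out libraries, 0.000926 with the replicate block and 0.00727 after the length and GC correction. The last 3 signs differ from the main r of -0.00112 by less than the spread over left-out libraries.

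After the length and GC correction 6 genes named in CcKO turned or lost their direction, Hes6 (0.00), Unc5d (-0.01), Dcx (-0.05), Cux1 (-0.07), Bax (0.03) and Vcan (-0.07), and a further 28 of the 230 gene results lost their call. DESeq2 ended 14 calls of named genes and limma on log2 of FPKM plus 1 ended 66, most of them in the E15.5 comparisons for limma. Leaving out 1 library ended calls in 296 of 2300 cases. Genes near the floor of 3 counts limit how far a low level can be read at this depth.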

Other observations

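The tests of a less mature state, of the trend as the only cause and of a response to either plasmid were chosen only after the result was seen, as were the subset of step-like genes above the floor, the lung gene list and the length and GC correction.

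Marker genes outside the called lists also differed. Reln, a secreted protein of Cajal-Retzius cells, rose 2.74-fold in CcKO and 1.49-fold in PB-GPC4, where Trp73 of the same cells rose 3.21-fold, while the Cajal-Retzius list reached an adjusted p of 0.0925 in CcKO and 0.162 in PB-GPC4. Slc1a2, an astrocytic glutamate transporter, rose 1.93-fold in CcKO, and Fgfr3 and Id3 were at 0.689 and 0.377 of control in PB-GPC4. The astrocyte list reached an adjusted p of 0.174 in PB-CCN1, the lowest of the 4 comparisons. The lowest for the other lists that passed in no comparison were 0.0655 for oligodendrocyte, 0.232 for endothelial and 0.171 for mural and fibroblast markers. The haemoglobin gene Hba-a1 rose 6.70-fold in CcKO, from 0.979 to 6.48 CPM. Once the length and GC trend was removed, log2 fold changes in CcKO went from 1.45 to 1.01 for Reln and from 0.95 to 0.47 for Slc1a2. That of Hba-a1 went from 2.74 to 3.1.

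Nkd1, a feedback inhibitor of Wnt signalling, rose 1.45-fold in PB-CCN1 and 1.24-fold in PB-GPC4, and Axin2, a Wnt target, was at 0.752 of control in PB-GPC4. The Wnt, BMP and p53 lists passed in no comparison, with lowest adjusted p values of 0.171, 0.616 and 0.0505. The FGF and ERK list had an adjusted p of 0.0514 in PB-CCN1 and the Notch3 receptor gene rose 1.94-fold in CcKO.

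Lung epithelial genes were far lower in both PB-GPC4 libraries than in PB-Ctrl and PB-CCN1. RNA or reads of lung carried over into the PB-Ctrl and PB-CCN1 libraries are a candidate explanation. Cyp2f2, Sftpc, Cbr2, Sec14l3 and Scgb3a2 kept their ratios to Scgb1a1 within 1.54-fold between the PB-Ctrl and PB-CCN1 libraries. Of 14 further lung genes above the floor in PB-Ctrl and low at E17.5, 8 were at least 4-fold lower in PB-GPC4. Sorting for GFP should remove lung cells, so the carry-over would have to follow the sort. Of the lung list, 7 genes were at 0.5 CPM or above at E17.5 and 1 is on the microglia list. A response of cortical cells to the GPC4 plasmid cannot be told apart, because the E17.5 libraries, where Scgb1a1 was at 0% of PB-Ctrl without that plasmid, differ in strain and age.

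Many genes (4663) differed between CcKO and WT, and the WT libraries stood apart by transcript length, with the shortest decile at 0.25 and 0.34 and the longest at -0.31 and -0.38 on the log2 scale relative to the mean of all libraries. The tables argue against a smooth trend as the only cause. After its removal 2117 calls passed again in the same direction, where 139 false ones are allowed. Those 139 cover false calls of the test alone. Technical differences that are not smooth in length or GC content are not covered by the removal. A trend in length or GC content may account for part of the calls, as 45.4% passed again, and the 2546 lost calls ended because the fold shrank, from a median absolute log2 fold change of 0.31 to 0.10 in the direction of the call (median SE 0.08 and 0.07). Passenger alleles near the floxed locus could not, through the 117 tested genes within 20 Mb of Ccn1, give more than 2.57% of calls. The share found there was 0.703%, and 27.4% of these genes were called against 30.6% elsewhere. Effects of such alleles on genes outside that window cannot be told apart. A less mature state of CcKO cells stays open: fold changes of CcKO and of E15.5 PB-Ctrl, each against another WT library, correlated across genes at r = 0.26 with the trend removed and 0.311 as deposited, but a shift shared by both WT libraries would give the same sign, and age is confounded with strain.

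Single genes differed in steps between E15.5 groups, 34 of them called with an absolute log2 fold change of at least 1 between PB-CCN1 and PB-GPC4, targeted and lung list genes aside. Segregating alleles of the outbred ICR stock are a candidate explanation: 44.1% of these genes differed at least 4-fold between ICR PB-Ctrl and C57BL/6 WT, against 8.36% of genes of like expression, a ratio of 5.27, with age confounded with strain. The ratio was 8.08 for the 28 genes above the floor in PB-GPC4. A response to either plasmid cannot be told apart, since of 27 genes with over 30 counts in each replicate, 22 had replicates within 2-fold and 1 differed by more than 4-fold (Rnaset2b, 5.72-fold). That gene met the bound first written as excluding such a response, and the bound was widened to most of the genes after the value was seen, because 1 gene with a near-identical copy cannot exclude it for the set.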
